A study of Homo sapiens with 24 samples.

How the data were processed

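Messenger RNA of 24 libraries from 4 cultures of kidney microvascular endothelial cells and 4 of HUVEC was sequenced, with a stranded poly(A) library kit on an Illumina instrument, per the labels' protocols. Per the submitters' processing notes, the authors named STAR 2.4.0c, featureCounts 1.4.3-p1, DESeq2 and genome build hg19, with no role or order given for them here. The gene annotation release behind the table was not given in the sources used here. The deposited file was 1 table of 57445 Ensembl gene identifiers by 24 columns of signal, here read counts that the authors divided by 1 size factor per library. All 24 columns matched a sample by title, and 0 columns were left unmapped. The values of each column were whole multiples of a fixed step within 1e-06, and 100% of them came out whole, so that the read counts and the depth of each library could be recovered. The libraries held 11.7 to 24.8 M reads.

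Gene symbols came from a table of gene names (51488 identifiers matched) and, for 324 more, from GENCODE release 29 on GRCh38. That reference differs in build from the table and served only for names, chromosome membership, and the length and GC content of the longest transcript. Genes on the Y chromosome and those of X inactivation (524 identifiers) and 5584 identifiers without a chromosome in the reference, 1380 of them with reads, were left out. The 28634 kept identifiers with reads held at least 99.5% of the reads of every library. Libraries of 1 group were compared before averaging, only to find a library deposited more than once. Over 36 pairs the lowest chi-square per degree of freedom was 15.0, so no pair was a repeat of 1 library within counting noise.

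The table held size-factor-normalised counts and not raw counts, so the tests were run with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(value + 1) of genes with a mean normalised value of at least 10. Count models were run on the recovered reads as alternatives: edgeR 4.0.16 quasi-likelihood with TMM, and DESeq2 1.42.0. Benjamini-Hochberg adjusted p-values under 0.05 were called. The 5 kidney comparisons came from 1 fit of 16 kidney libraries (13937 genes, 9 residual degrees of freedom). The VEGF effect in HUVEC and its difference from that in kidney cells came from 1 fit of 16 vehicle libraries (13905 genes, 6 residual degrees of freedom). Both fits held the culture as a block, since libraries with the same culture letter came from the same culture per the labels. Over 24 pairs of kidney libraries of 1 culture the lowest correlation of deviations from the group means was 0.734, and over 4 pairs of HUVEC libraries it was 0.619. The comparisons of HUVEC with kidney cells used 8 libraries each, without a block (13896 and 13916 genes, 6 residual degrees of freedom). Where the labels did not settle the number of HUVEC donors, p-values for HUVEC measured the spread between cultures. Fold changes are on the log2(value + 1) scale. For genes with 0 reads in a group, the fold is a bound against a floor of 3 reads per library, which covers counting error only. Genes with near-identical copies or overlapping neighbours share reads in ways the table does not show.

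The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule took, per comparison, up to 12 higher and 12 lower genes with the largest called change, a mean of at least 50 in the higher group and the same direction in all 4 pairs or no overlap between groups. For the differences between responses it took the 5 smallest p-values per direction. It also took the members of the fixed lists, and FOXO1, FLT1, KDR, DLL4, ANGPT2 and ESM1 in every comparison. Genes whose level can follow a person's genotype were not named. Which of the allowed genes the text names was chosen after their values were seen, and the checks of single samples cover only these. The 26 lists held 314 members, 304 with reads among the kept identifiers: immediate early, ERK feedback, calcineurin-NFAT and early VEGF response, NF-kB inflammatory, tip cell, stalk cell and Notch, FOXO target, FOXO family, VEGF ligand and receptor, BMP-TGFb response, shear-responsive, pericellular proteolysis and matrix, glycolysis, sterol synthesis, cell cycle and heat shock genes, and markers of pan-endothelial, arterial, venous, renal microvascular, lymphatic, fibroblast, mural, kidney epithelial, podocyte and leukocyte cells. PECAM1, TXNIP, GJA5 and HSPA1A were among the members not found there, which need not mean that they were not expressed. Lists with at least 3 measured members were tested with camera, with a preset correlation of 0.01 and with an estimated one.

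Alternatives were pseudocounts of 0.5 and 5, no filter and a mean of at least 50, quantile normalisation, edgeR, DESeq2, each culture left out in turn, no block, only the 8 libraries of a comparison, and HUVEC averaged by donor label. Added after the data were seen were a length and GC trend removed from each library and a fit without the 2 shallowest libraries. The tests of 4 comparisons were tested on simulated data drawn from the real means and depths. Each gene was drawn on its own, without a length or GC trend between libraries of 1 culture. In these data 200 genes with a mean of at least 50 were changed by 1.5, 2 or 4 times. The other 5 comparisons were not simulated. For VEGF under vehicle in kidney cells (13858 genes) limma found 88.1, 98.5 and 100% of them, with 2.05% of calls false. For the difference between responses (13867 genes) it found 68.7, 95.5 and 100%, with 8.81% false. For VEGF in HUVEC (13824 genes) the shares were 77.6, 100 and 100%, with 3.65% false. For HUVEC against kidney cells without VEGF (13720 genes) they were 7.5, 35.8 and 89.4%, with 4.35% false for limma and 25.7% for DESeq2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.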

Results

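The data set held 24 polyadenylated RNA sequencing libraries from cultured human endothelial cells, the cells that line blood vessels. Kidney microvascular endothelial cells from 4 donor cultures, called A to D here, each gave 4 libraries. Human umbilical vein endothelial cells (HUVEC), a standard large-vessel comparison, gave 2 libraries from each of 4 cultures, called E to H. Confluent cells were starved of serum for 4 h and held for 60 min in 0.1% DMSO, the vehicle, or in 0.5 µM AS1842856, an inhibitor of the transcription factor FOXO1. They were then left without or given 50 ng/ml of vascular endothelial growth factor (VEGF) for 30 min. Whether cells without VEGF were held for the same further 30 min was not stated. An effect of that time or handling cannot be set apart from that of VEGF. This made 6 groups of 4 libraries: kidney cells under vehicle or inhibitor, each without and with VEGF, and HUVEC under vehicle without and with VEGF. The libraries held 11.7 to 24.8 mega-reads (M) assigned to genes, with a median of 20.2 M, and by group 19.8 ± 2.87 and 20.5 ± 1.05 M in kidney cells under vehicle without and with VEGF, 18.9 ± 2.85 and 17.0 ± 4.57 M under the inhibitor, and 19.2 ± 2.93 and 21.7 ± 2.10 M in HUVEC. The deposited values were normalised read counts, and levels are given below as their mean ± SD over the 4 cultures of a group. Fold changes were computed on log2(value + 1) and averaged on that scale, so they can lie below or above the ratio of the means, and are given as the level in the treated group relative to its control. The deposited table names genes by Ensembl identifier, on genome build hg19 per the submitters' processing notes, without positions, so no positions are given here. The labels count 4 HUVEC cultures by title while a second label names 2 HUVEC donors, each for 2 cultures, so it was not settled whether the 4 HUVEC cultures came from 4 donors or 2.

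The first question was which transcripts kidney microvascular endothelial cells change within 30 min of VEGF under vehicle. Transcription factors of the immediate early class, which are induced without new protein synthesis, rose most. EGR3 (ENSG00000179388) went from 3.24 ± 3.28 to 3575 ± 2736 normalised counts (863-fold, log2 change 9.75, SE 0.18, n = 4, higher in 4 of 4 cultures, limma adjusted p = 9.21e-18). EGR1 (ENSG00000120738) went from 168 ± 63.2 to 10320 ± 3013 (62.8-fold, log2 change 5.97, SE 0.13, limma adjusted p = 4.21e-17, higher in 4 of 4 cultures). EGR2 rose 404-fold, FOS 114-fold, the nuclear receptor NR4A1 53.1-fold and ZFP36, whose product destabilises AU-rich mRNAs, 40.6-fold. EGR2 and EGR3 had 12 reads each over the 4 unstimulated libraries, so the size of their folds depends in part on the 1 added to each value. EGR4 had 0 reads in all 4 unstimulated libraries and reached 54.3 ± 70.9, which made it at least 18.1-fold higher over a floor of 3 reads per library, and at least 7.05-fold without culture B, where the mean was 19.2. Of the 23 measured immediate early genes 21 passed the test over all genes tested, all higher, and 22 when adjusted over the list alone.

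**Figure D1:**
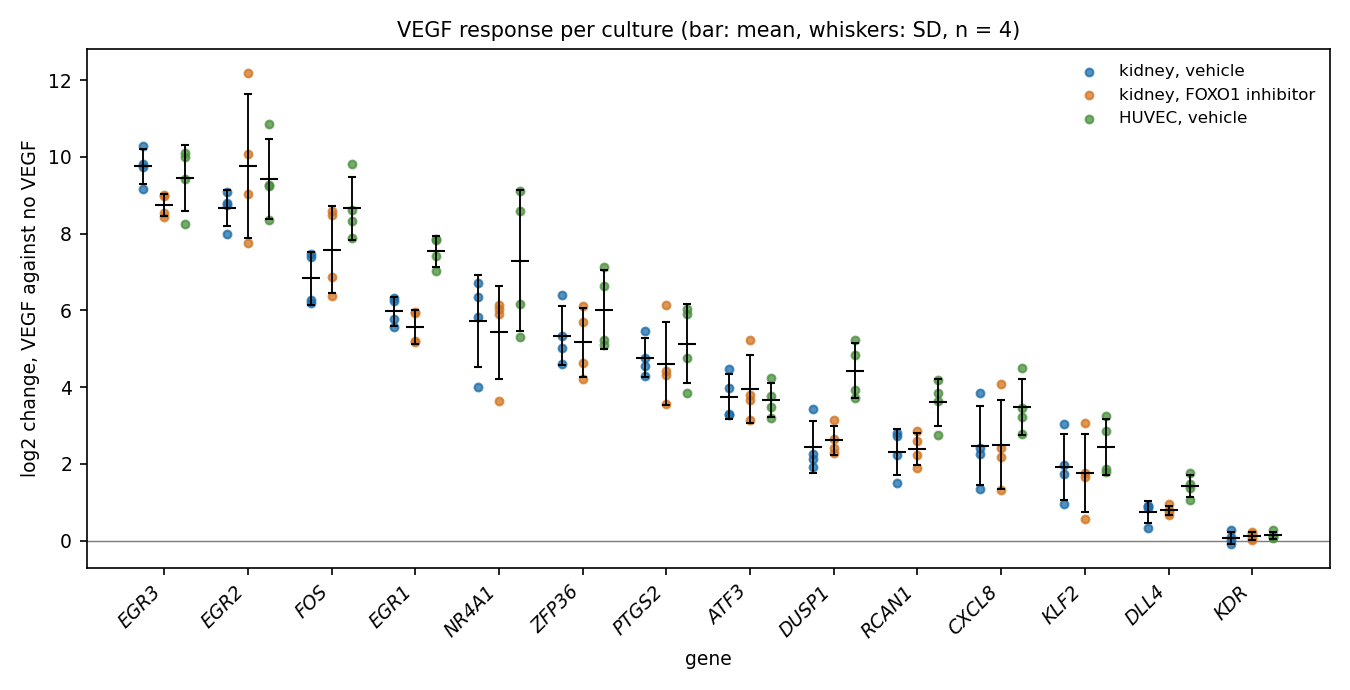
Log2 change with VEGF (y axis) of 14 genes (x axis), with 1 point per culture, a bar at the mean and whiskers of 1 SD over 4 cultures, for kidney cells under vehicle, kidney cells under the FOXO1 inhibitor and HUVEC under vehicle. EGR3 lay at a mean of 9.75, 8.74 and 9.44 in these settings, and KDR lay at 0.07, 0.12 and 0.14.

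Inducible brakes on signalling rose with them under vehicle. Among 14 negative feedback genes of the ERK kinase pathway 7 passed, all higher (9 adjusted over the list alone), with DUSP1 at 5.38-fold, DUSP5 at 3.73-fold and SPRY4 at 3.36-fold. Among 14 calcineurin-NFAT and early VEGF response genes 10 passed, all higher (10 adjusted over the list alone), among them the prostaglandin synthase PTGS2 at 27.2-fold, APOLD1 at 8.60-fold and the calcineurin inhibitor RCAN1 at 4.97-fold. Among 16 inflammatory NF-kB genes 11 passed, all higher (14 adjusted over the list alone), with the chemokines CXCL2 at 15.4-fold (10.2-fold without B) and CXCL8 at 5.53-fold, NFKBIZ at 7.47-fold and IL6 at 4.43-fold. These 4 lists shifted relative to all other genes in the camera test, both with the preset correlation (adjusted p of 3.87e-67 for immediate early, 6.69e-15 for ERK feedback, 3.29e-20 for NFAT and 8.50e-18 for NF-kB genes) and with an estimated correlation (adjusted p = 0.00159, 0.00662, 0.00135 and 0.0481 in the same order).

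Vessel sprouting genes were compared next. The Notch ligand DLL4, a marker of the leading tip cell of a sprout, rose from 1395 ± 570 to 2282 ± 769 (1.68-fold, limma adjusted p = 2.90e-05, higher in 4 of 4 cultures), and the Notch target HEY1 rose 1.56-fold. The shear-responsive factors KLF2 and KLF4 rose 3.79-fold and 4.58-fold. The VEGF receptors KDR (1.05-fold, adjusted p = 0.547) and FLT1 (1.00-fold, adjusted p = 0.988), and ANGPT2 (1.05-fold), ESM1 (1.11-fold) and FOXO1 itself (1.12-fold, adjusted p = 0.132), did not pass. Of the 19 tip cell genes 2 passed, DLL4 and HLX, both higher. With 3 adjusted over the list alone, that list passed with the preset correlation (adjusted p = 0.00750) but not with an estimated one (adjusted p = 0.339). Of 21 FOXO target genes TRIB1, BCL6 and CITED2 rose and GADD45A fell to 0.742 of its level (6 higher and 2 lower adjusted over the list alone). This list, at an adjusted p = 0.00707 with the preset correlation, had an adjusted p = 0.112 with an estimated correlation. The 4 shear-responsive genes (adjusted p = 0.000140 preset and p = 0.112 estimated) and the 11 glycolysis genes, shifted down with 0 members passing (p = 0.00625 preset and p = 0.490 estimated), likewise kept their call only with the preset correlation. No other list was called under vehicle.

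In all, 330 of 13937 genes changed with VEGF under vehicle, 305 higher and 25 lower, and 66 of the higher ones by over 2-fold. Transcripts over 8 kb had a median log2 change of 0.11 and those under 2 kb of -0.08. Of the 305 higher genes 88 had transcripts over 8 kb, and of the 25 lower genes 0 did, against 1218 of all 13937 genes tested. The count moved with the cultures used and with the pairing of libraries by culture (the block). It was 599, 171, 174 and 142 without culture A, B, C or D, 22 without the block, and 507 with DESeq2. Lower genes numbered 144 without A, 5 without B, 0 without C, 3 without D, 81 with DESeq2, 52 with quantile normalisation and 43 with a trend of length and GC content removed, and the share of higher genes was 92.4% in full and 76% without A. With that trend removed 192 genes were higher, 81.7% of 235. The call of GIMAP6 (0.825 of its level) was lost without culture A, C or D, that of SNRPA (0.821) without B or C, and that of GADD45A without C. The calls of HEY1 and HLX were lost without B, C or D. Without the block those of DLL4, KLF2, KLF4, CXCL2, CXCL8, IL6, RCAN1, DUSP5, BCL6, CITED2, HEY1, HLX and the 3 lower genes were lost.

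The same stimulation under the FOXO1 inhibitor asked whether the response needs FOXO1 activity at the level that the inhibitor leaves. The leading genes were again immediate early factors. EGR2 rose 870-fold (497-fold without B and 1389-fold without D), EGR3 428-fold (from 8.91 ± 5.72 to 4266 ± 2915, limma adjusted p = 7.11e-17, higher in 4 of 4 cultures), FOS 191-fold, EGR1 47.3-fold, NR4A1 43.0-fold (65.2-fold without A), PTGS2 24.4-fold and ATF3 15.4-fold. EGR2 had 8 reads in all over the 4 libraries without VEGF. The size of its fold rests largely on the 1 added to each value, and cannot be set against that under vehicle. DLL4 rose 1.73-fold (from 1199 ± 352 to 2068 ± 613, adjusted p = 1.38e-05). FLT1 (1.02-fold), KDR (1.09-fold), ANGPT2 (0.929 of its level), ESM1 (1.12-fold) and FOXO1 (1.15-fold) did not pass. Of the immediate early genes 21 of 23 passed, all higher, as did 8 of 14 ERK feedback, 9 of 14 NFAT and 10 of 16 NF-kB genes (23, 9, 10 and 12 adjusted over each list alone). Of the 21 FOXO targets 4 rose (5 higher and 1 lower adjusted over the list alone): TRIB1 5.17-fold, BCL6 2.12-fold, CITED2 2.04-fold and the metabolic kinase PDK4 2.00-fold. The call of PDK4 was lost without culture A, C or D.

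These 5 lists passed in the camera test with both correlation settings, with adjusted p = 0.000304, 0.00172, 0.000236, 0.0182 and 0.0306 with an estimated correlation. The arterial markers passed too, where 3 of 9, EFNB2, DLL4 and HEY1, rose (3 adjusted over the list alone, camera adjusted p = 0.0461 with an estimated correlation), as did pericellular proteolysis and matrix genes, where 3 of 18, ADAMTS1, PLAU and ADAMTS4, rose (5 adjusted over the list alone, camera adjusted p = 0.0338 with an estimated correlation, and p = 0.448 without the block). Tip cell, stalk cell and Notch, BMP-TGFb, shear-responsive, renal microvascular, lymphatic and fibroblast lists were called only with the preset correlation. Their adjusted p with an estimated correlation was 0.113, 0.0800, 0.166, 0.0575, 0.0575, 0.113 and 0.303. In all, 186 of 13937 genes changed, 180 higher and 6 lower, and 146 of the higher genes were also among the 305 under vehicle, where 3.94 would be shared by independent lists. Both lists came from the same 4 cultures and 1 fit, so they were not independent. Lower genes included DDIT4 (0.636 of its level) and ARSK (0.714), both lost without culture B, C or D. Without culture B or D the count was 105 or 123, without the block 26, with the calls of DLL4, BCL6, CITED2, HEY1 and ADAMTS1 among those lost, and without the 2 shallowest libraries 117. The call of PLAU was also lost without culture A, B or D, and that of ADAMTS4 without B or C. Transcripts over 8 kb had a median log2 change of -0.005.

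A further comparison asked what the inhibitor did without VEGF. FOXO targets fell. The ubiquitin ligase FBXO32, a classical FOXO target, fell from 142 ± 62.7 to 37.0 ± 19.3 (0.258 of its level, log2 change -1.95, SE 0.28, limma adjusted p = 4.61e-04, lower in 4 of 4 cultures). PDK4 fell to 0.332, the cyclin CCNG2 to 0.464 (adjusted p = 5.07e-08), CITED2 to 0.540, KLHL24 to 0.578 and the cell cycle inhibitor CDKN1B to 0.647 of their levels. Of the 21 measured FOXO targets 10 passed, all lower (12 adjusted over the list alone), and the list passed with both correlations (adjusted p = 1.82e-14 preset and p = 0.00178 estimated). Several genes outside the list fell as far. The nuclear receptor coactivator PNRC1 (ENSG00000146278) fell from 754 ± 101 to 183 ± 50.5 (0.238 of its level, limma adjusted p = 5.10e-09). CREBRF fell to 0.414, FRAT2 to 0.415, DEPP1 to 0.438, TGIF1 to 0.447, BMP4 to 0.484 and the kinase PIM1 to 0.485. FOXO1 mRNA itself fell to 0.742 of its level (1720 ± 294 to 1282 ± 254, limma adjusted p = 1.53e-04, lower in 4 of 4 cultures), and FOXO3 to 0.751, a call lost without culture A, B or D. With 2 of 3 members lower the FOXO family list had an adjusted p = 8.50e-04 with the preset and p = 0.242 with an estimated correlation.

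Rises with the inhibitor were smaller. The AP-1 factor FOSL1 rose 1.60-fold, the growth factor PDGFA 1.52-fold and the repressor BCL6B 1.46-fold (2678 ± 812 to 3926 ± 1268, limma adjusted p = 1.75e-04, higher in 4 of 4 cultures). The clock gene PER2 rose 2.05-fold, a call lost without culture B or C. The 17 cell cycle genes and the 9 arterial markers shifted down with the preset correlation only (camera adjusted p = 0.890 and p = 0.242 with an estimated correlation), with 0 cell cycle genes and 1 arterial marker passing, EFNB2, a call lost without culture A, C or D. FLT1 (0.980 of its level), KDR (0.919), DLL4 (0.896), ANGPT2 (1.04-fold) and ESM1 (0.787, adjusted p = 0.0975) did not pass. In all, 306 of 13937 genes changed, 117 higher and 189 lower, 3 and 15 of them by over 2-fold. Of the 117 higher genes 51 were also higher with VEGF under vehicle, where independent lists would share 2.56. The lower lists of these 2 comparisons shared 2 genes, where independent lists would share 0.34. Both comparisons are set against the same 4 vehicle libraries without VEGF, so their lists were not independent. Transcripts over 8 kb had a median log2 change of 0.07 and gave 41 of the 117 higher genes and 10 of the 189 lower ones. Among all 13937 genes tested they numbered 1218. The call of the FOXO target IRS2 (0.427 of its level) was lost without culture B, C or D. Counts without culture A, B, C or D were 185, 149, 177 and 112, without the block 2, PNRC1 and FRAT2, and without the 2 shallowest libraries 183. With only the 8 libraries of the comparison the count was 172.

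**Figure D2:**
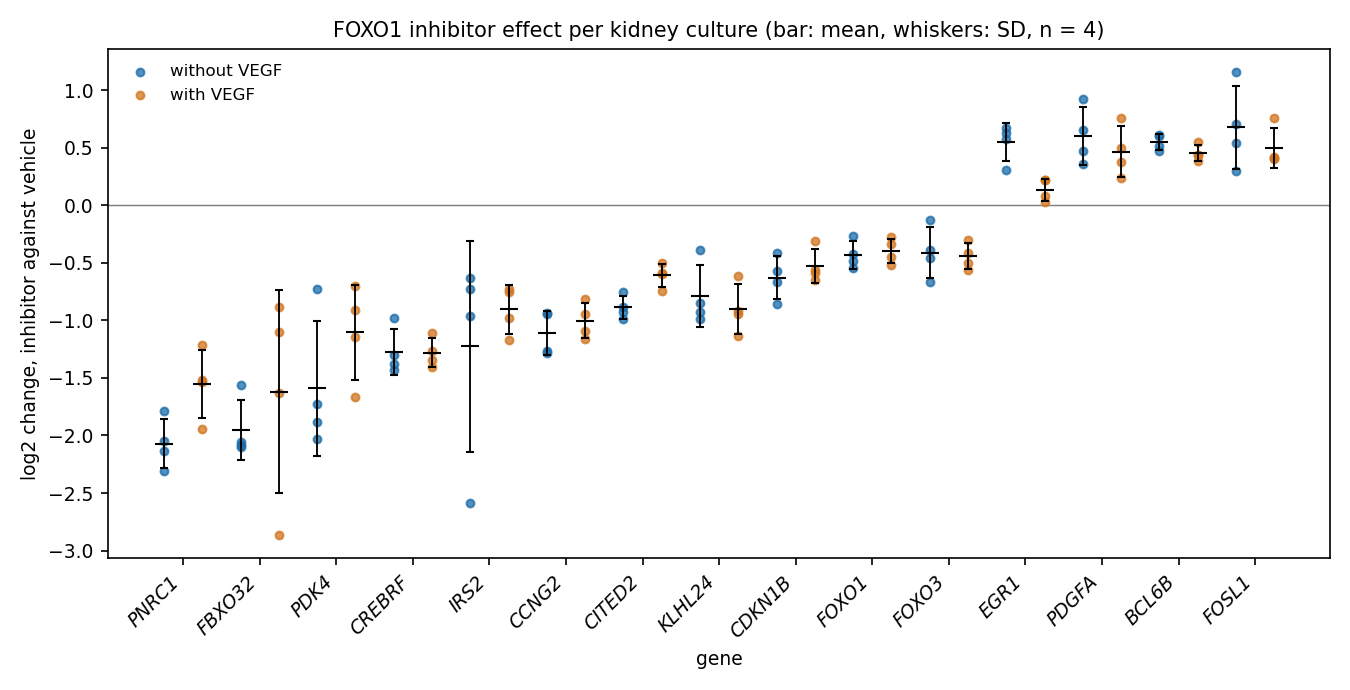
Log2 change of kidney cells under the FOXO1 inhibitor against vehicle (y axis) for 15 genes (x axis), with 1 point per culture, a bar at the mean and whiskers of 1 SD over 4 cultures, without and with VEGF. PNRC1 lay at a mean of -2.07 without VEGF and -1.55 with VEGF, and FOXO1 at -0.43 and -0.40.

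With VEGF the inhibitor lowered much the same set. PNRC1 fell to 0.341 of its level under vehicle (931 ± 210 to 331 ± 139, limma adjusted p = 2.81e-07, lower in 4 of 4 cultures), CREBRF to 0.412, TGIF1 to 0.482, CCNG2 to 0.499, the MAX-binding repressor MNT to 0.523 and KLHL24 to 0.535. FBXO32 fell to 0.326 and PDK4 to 0.465, calls lost without culture D for both and without C for PDK4. FOXO1 fell to 0.759 (limma adjusted p = 5.65e-04). The stress cytokine GDF15 rose 1.47-fold and BCL6B 1.37-fold, and PDGFA rose 1.38-fold, a call lost without culture B, C or D. FLT1 (1.00-fold), KDR (0.953 of its level), DLL4 (0.921), ANGPT2 (0.922) and ESM1 (0.794) did not pass. Of the 21 FOXO targets 7 passed, all lower (11 adjusted over the list alone), with adjusted p = 8.75e-19 preset and p = 6.32e-04 with an estimated correlation. The FOXO family list, with FOXO1 and FOXO3 lower, was called only with the preset correlation (camera adjusted p = 0.192 with an estimated correlation). No other list was called.

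Here 145 of 13937 genes changed, 23 higher and 122 lower. The lower lists without and with VEGF shared 97 genes, where independent lists would share 1.65. The higher lists shared 15, where independent lists would share 0.19. Counts without culture B, C or D were 53, 78 and 65. Without the block the count was 0 with limma, and 187 genes had an unadjusted p under 0.05. It was 227 with DESeq2 and 83 without the 2 shallowest libraries.

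Whether the inhibitor changed the VEGF response was tested as the difference between the responses under inhibitor and vehicle. No gene passed with limma, where 960 genes had an unadjusted p under 0.05 against 697 by chance, and the smallest adjusted p was 0.259. edgeR called 0 and DESeq2 14 genes. On simulated reads with the same design, limma found 68.7% of genes made 1.5-fold different and 95.5% of those made 2-fold different. These genes had a mean of at least 50, while the test covered genes with a mean of at least 10. The simulation held no length or GC trend between libraries of 1 culture, so these shares need not hold for all genes tested. The smallest p-values belonged to CCN1 (1.24 times larger response under the inhibitor, log2 difference 0.32, SE 0.06) and to MACF1 (0.775), WDFY3 (0.807) and HOOK3 (0.772), all 4 with a limma adjusted p = 0.259. DLL4 had a log2 difference of 0.04 (SE 0.13), ESM1 of 0.01 (SE 0.15), ANGPT2 of -0.17 (SE 0.10), FLT1 of 0.03 (SE 0.07), KDR of 0.05 (SE 0.08) and FOXO1 of 0.03 (SE 0.08). No list was called with either correlation. For the FOXO targets the camera adjusted p was 0.884 with the preset correlation. Adjusted over each list alone, 1 of 23 immediate early genes had a smaller response under the inhibitor. In the same way 1 of 14 BMP-TGFb genes had a larger one, and no member of any other list tested passed. Transcripts over 8 kb had a median difference of -0.10 and those under 2 kb of 0.07.

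In HUVEC under vehicle VEGF raised the same classes of gene. EGR3 rose 696-fold (4.74 ± 1.96 to 4269 ± 2292), EGR2 688-fold, FOS 403-fold, EGR1 186-fold (46.5 ± 26.7 to 9396 ± 6635, log2 change 7.54, SE 0.14, limma adjusted p = 3.48e-12, higher in 4 of 4 cultures), NR4A1 157-fold (103-fold without F and 248-fold without H) and NR4A2 103-fold. EGR3 had 20 and EGR2 6 reads over the 4 libraries without VEGF, so the size of these 2 folds too depends in part on the added 1. PTGS2 rose 35.0-fold, CXCL2 28.0-fold, DUSP1 21.5-fold, RCAN1 12.2-fold, the coagulation initiator F3 12.1-fold, CXCL8 11.2-fold, DUSP5 10.1-fold and the metalloprotease ADAMTS1 7.74-fold. Of 16 stalk cell and Notch genes 3 rose, HEY1 2.95-fold, NRARP 1.98-fold and JAG1 1.39-fold (4 adjusted over the list alone, camera adjusted p = 0.143 with an estimated correlation). DLL4 rose 2.67-fold (936 ± 381 to 2696 ± 1560, adjusted p = 5.69e-06). KLF4 rose 9.31-fold, KLF2 5.41-fold and thrombomodulin, THBD, 1.75-fold, the last lost without culture F. FOXO1 (1.12-fold), FLT1 (0.950 of its level), KDR (1.1-fold), ANGPT2 (0.971) and ESM1 (0.996) did not pass.

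Of the immediate early genes 21 of 23 passed in HUVEC, all higher, with 9 of 14 ERK feedback, 9 of 14 NFAT and 8 of 16 NF-kB genes (23, 9, 10 and 11 adjusted over each list alone), and adjusted p = 0.0193, 0.0319, 0.0170 and 0.0319 with an estimated correlation. Of 21 FOXO targets 5 rose, among them TRIB1 at 6.82-fold and CITED2 at 2.70-fold, with 6 higher and 3 lower adjusted over the list alone and a median log2 change of 0.03 (camera adjusted p = 0.0420 with an estimated correlation). So did 3 of 4 shear-responsive genes (3 adjusted over the list alone, camera adjusted p = 0.0319 with an estimated correlation) and 3 of 9 arterial markers (5 adjusted over the list alone, camera adjusted p = 0.0463 with an estimated correlation). These lists share members with others, such as KLF4 with the immediate early list and DLL4 with the tip cell list. Tip cell, stalk cell and Notch, BMP-TGFb and proteolysis lists were called only with the preset correlation, with camera adjusted p = 0.0720, 0.143, 0.296 and 0.240 with an estimated correlation. In all, 205 of 13905 genes changed, 200 higher and 5 lower. Of the higher genes 126 were also higher in kidney cells under vehicle, where independent lists would share 4.43. The kidney vehicle libraries entered both fits, so these lists were not wholly independent. DEPP1 fell to 0.532 of its level, a call lost without culture F. The count was 46 without the block, where DLL4, HEY1, NRARP, JAG1, KLF4 and F3 lost their calls, and 152 with HUVEC cultures averaged by donor label.

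The difference between the responses of HUVEC and kidney cells was tested within vehicle. Over all genes tested, EGR1 alone passed. Its response was 2.95 times as large in HUVEC (log2 difference 1.56, SE 0.20, limma adjusted p = 0.0476, higher in all 4 HUVEC than in all 4 kidney cultures). Its call was lost when any 1 of cultures A to F was left out, without the block, with a pseudocount of 0.5, without the filter on low values, with a minimum mean of 50 and with quantile normalisation. ADAMTS1 (log2 difference 2.33, SE 0.34, adjusted p = 0.0910), F3 (2.4, SE 0.42), DUSP1 (2.00, SE 0.34) and JUNB (1.27, SE 0.22, the last 3 at an adjusted p = 0.171) had larger responses in HUVEC, and the lymphocyte activation antigen CD69 a smaller one (-2.31, SE 0.41, adjusted p = 0.171), without passing. DLL4 had a log2 difference of 0.67 (SE 0.15, adjusted p = 0.469), FOXO1 of 0.00 (SE 0.09), FLT1 of -0.08 (SE 0.08), KDR of 0.07 (SE 0.08), ANGPT2 of -0.11 (SE 0.12) and ESM1 of -0.16 (SE 0.11). Immediate early, ERK feedback, NFAT, glycolysis and arterial lists were shifted towards HUVEC with the preset correlation (adjusted p = 1.62e-06, 8.21e-07, 4.78e-05, 4.78e-05 and 0.0244). None was with an estimated correlation (p = 0.682 for immediate early genes and p = 0.413 for the rest). Adjusted over each list alone, 6 of 23 immediate early, 7 of 14 ERK feedback, 5 of 14 NFAT and 4 of 9 arterial genes had larger responses in HUVEC. In the same way 1 NFAT gene had a smaller one, and 0 of 11 glycolysis genes passed. The arterial and glycolysis shifts were also lost without the block, at adjusted p-values of 0.391 and 0.154. limma gave 1305 genes with an unadjusted p under 0.05 against 695 by chance. edgeR called 3 genes, DESeq2 12, and limma 12 with HUVEC cultures averaged by donor label, 2 without culture G and 7 without culture H.

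Baseline differences between HUVEC and kidney cells, without VEGF and under vehicle, were large, and tissue, donor and culture cannot be separated in them. Of the 18 proteolysis and matrix genes 6 were lower in HUVEC and 0 higher (1 higher and 13 lower adjusted over the list alone, camera adjusted p = 0.160 with an estimated correlation). COL1A1 (ENSG00000108821) averaged 32750 ± 44070 in kidney cells and 18.1 ± 12.0 in HUVEC (log2 difference -10.03, SE 0.83, limma adjusted p = 3.65e-04, no overlap between the 4 and 4 cultures). Culture B held 98400 of it against 5146 to 17730 in the other 3, and without B the log2 difference was -9.19 for COL1A1 and -11.06 in place of -11.97 for COL6A3. COL6A3 averaged 21320 ± 31240 against 2.01 ± 1.62, VCAN 2785 ± 2326 against 5.94 ± 2.66 (log2 difference -8.18, and -8.87 without A), and the BMP antagonist GREM1 2795 ± 2169 against 0 reads in all 4 HUVEC libraries, at least 929-fold lower. The transcription factor SOX11 was at least 108-fold lower in HUVEC, also with 0 reads. The basement membrane chains COL4A1 and COL4A2 averaged 92690 ± 23250 and 62820 ± 13680 in kidney cells and 13500 ± 4361 and 13860 ± 4088 in HUVEC. In the other direction the retinoic acid enzyme ALDH1A2 was 117-fold higher in HUVEC (1789 ± 199 against 46.0 ± 50.7, a ratio of the means of 38.9, and 47.0-fold, 219-fold and 202-fold without culture B, C or D), MGP 32.1-fold (56.9-fold without B), TBX1 25.04-fold and BMX, an arterial marker, 9.49-fold. ALDH1A2 lost its call with HUVEC averaged by donor label.

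Of 8 renal microvascular and fenestrated endothelial markers 5 were lower in HUVEC and 0 higher (the same adjusted over the list alone): PLVAP, the diaphragm protein of fenestrae, at 155 ± 116 against 3752 ± 2333, with LPL, IGFBP5, TBX3 and NOSTRIN (camera adjusted p = 0.152 with an estimated correlation). Of 9 arterial markers 2 were higher and 3 lower in HUVEC. None of the 12 measured pan-endothelial markers passed, and PECAM1 was not among those measured. CDH5 averaged 30300 ± 6562 in kidney cells and 22840 ± 3211 in HUVEC, and VWF 43870 ± 38360 and 115500 ± 63420. FLT1 was at 0.413 of the kidney level in HUVEC (1945 ± 135 against 4944 ± 1841) and ANGPT2 at 0.217 (0.329 without A), a call lost without D, E, F, G or H. KDR (0.804), DLL4 (0.679), ESM1 (0.684) and FOXO1 (1.83-fold, adjusted p = 0.164) did not pass. Markers of other cells moved with the tissue. Of 8 fibroblast markers PDGFRB, COL1A1, THY1 and FAP were lower in HUVEC (1 higher and 4 lower adjusted over the list alone), and of 6 mural cell markers CSPG4, TAGLN, CNN1 and NOTCH3 were lower while RGS5 was 8.46-fold higher (1 higher and 5 lower adjusted over the list alone). The calls of THY1 (without B, C, D or H), CNN1 (without B to H), NOTCH3 (without E or H) and RGS5 (without E, F or H) were lost in this way. Of 9 kidney epithelial and 4 venous markers 0 passed, of 4 lymphatic markers RELN alone, and 2 podocyte markers were too few to test. No leukocyte marker reached the mean normalised value of 10 needed for testing in any comparison.

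**Figure D3:**
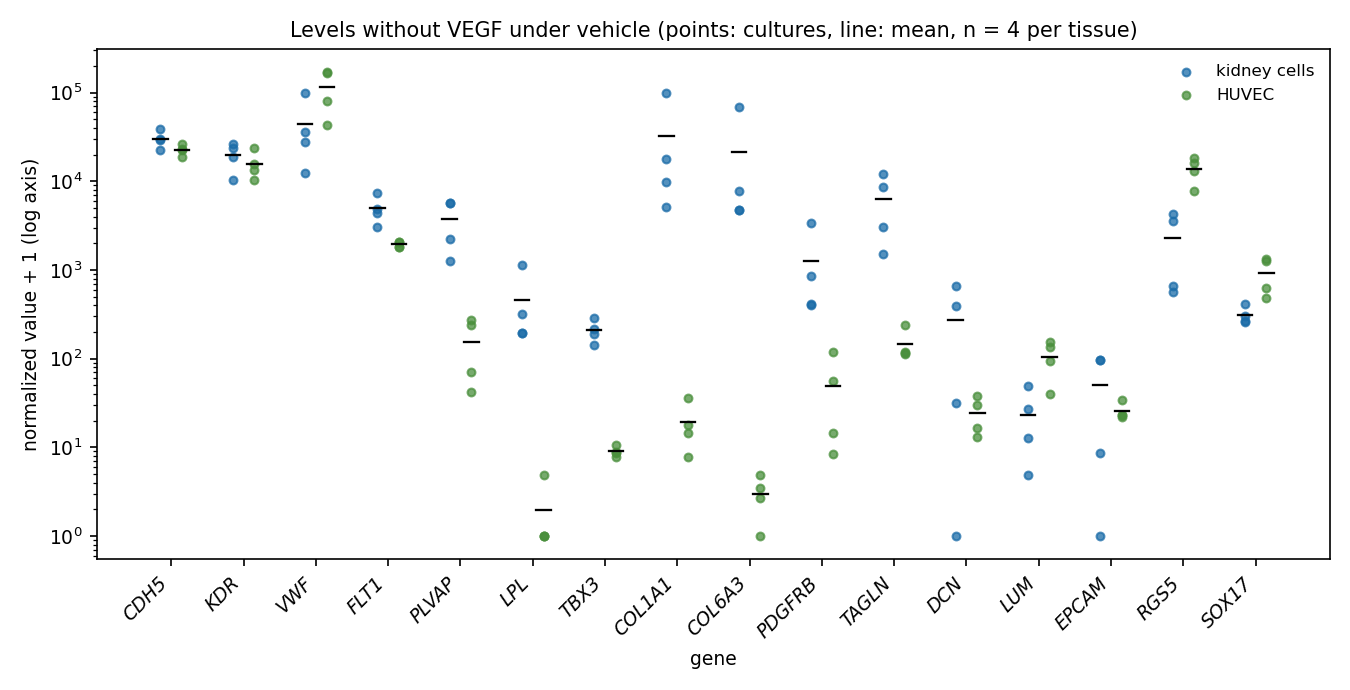
Normalised values plus 1 on a log axis (y axis) of 16 genes (x axis) without VEGF under vehicle, with 1 point per culture and a line at the mean, for 4 kidney and 4 HUVEC cultures. COL1A1 lay between 5146 and 98397 in kidney cells and averaged 18.1 in HUVEC, while CDH5 averaged 30300 and 22840.

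Signalling genes differed before stimulation as well. Of 20 immediate early genes 6 were lower in HUVEC and BTG2 higher, a call lost with HUVEC averaged by donor label, with EGR1 at 0.256 of the kidney level, a call lost without B, C, D, F or H. The NF-kB genes had 5 of 15 lower, including VCAM1 (41.4 ± 43.0 against 1305 ± 837) and CXCL8 (82.6 ± 22.6 against 1435 ± 1006), and the NFAT genes 6 of 14 lower and 1 higher. Lower lists in HUVEC with the preset correlation were immediate early, ERK feedback, NFAT, NF-kB, tip cell, stalk cell and Notch, BMP-TGFb, proteolysis, glycolysis, renal microvascular, fibroblast and mural, and sterol synthesis was higher. None was called with an estimated correlation, where the smallest adjusted p was 0.152, for the NFAT and renal microvascular lists. In all, 1279 of 13896 genes differed, 498 higher and 781 lower in HUVEC, 306 and 612 of them by over 2-fold. With quantile normalisation 643 were higher and 706 lower, a share of 47.7% higher against 38.9%. DESeq2 called 2304, and HUVEC averaged by donor label gave 585. Counts without culture F, G or H were 723, 797 and 809.

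With VEGF the comparison of HUVEC and kidney cells looked alike. The 2 comparisons shared 320 higher and 607 lower genes. They used the same 8 cultures, so their lists were not independent. ALDH1A2 was 119-fold higher in HUVEC (48.5-fold and 250-fold without B or C), and the chaperone CLU 16.8-fold (39000 ± 36110 against 2331 ± 2567, 26.3-fold without B). COL1A1 averaged 14.1 ± 3.80 against 30690 ± 34440 (log2 difference -10.45, and -9.78 without B), GREM1 was at least 1064-fold lower with 0 reads in HUVEC, and PLVAP averaged 150 ± 109 against 3133 ± 1573. CD69 averaged 8.62 ± 3.67 in HUVEC and 561 ± 388 in kidney cells. Among FOXO targets FBXO32 was 4.77-fold higher in HUVEC, a call lost without B, E or H. EGR1 no longer differed by the test (0.757 of the kidney level, adjusted p = 0.681), and of 23 immediate early genes FOSL1 alone passed, lower, a call lost without A, B, C, G or H. FLT1 stood at 0.392 of the kidney level (limma adjusted p = 0.00370) and ANGPT2 at 0.202 (lost without F or H), while KDR (0.842), DLL4 (1.08-fold), ESM1 (0.612) and FOXO1 (1.82-fold) did not pass. Markers of other cells again moved with the tissue, with 4 of 9 fibroblast markers lower and LUM higher in HUVEC (lost without A, B, D, F, G or H), and 4 of 6 mural markers lower. NF-kB, stalk cell and Notch, proteolysis, renal microvascular, fibroblast and mural lists were lower and sterol synthesis higher with the preset correlation. None was with an estimated correlation, where the smallest adjusted p was 0.249. In all, 1216 of 13916 genes differed, 423 higher and 793 lower. With quantile normalisation 596 were higher and 693 lower, a share of 46.2% higher against 34.8%. DESeq2 called 2254, HUVEC averaged by donor label gave 697, and leaving out culture F or H gave 718 or 729.

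**Figure D4:**
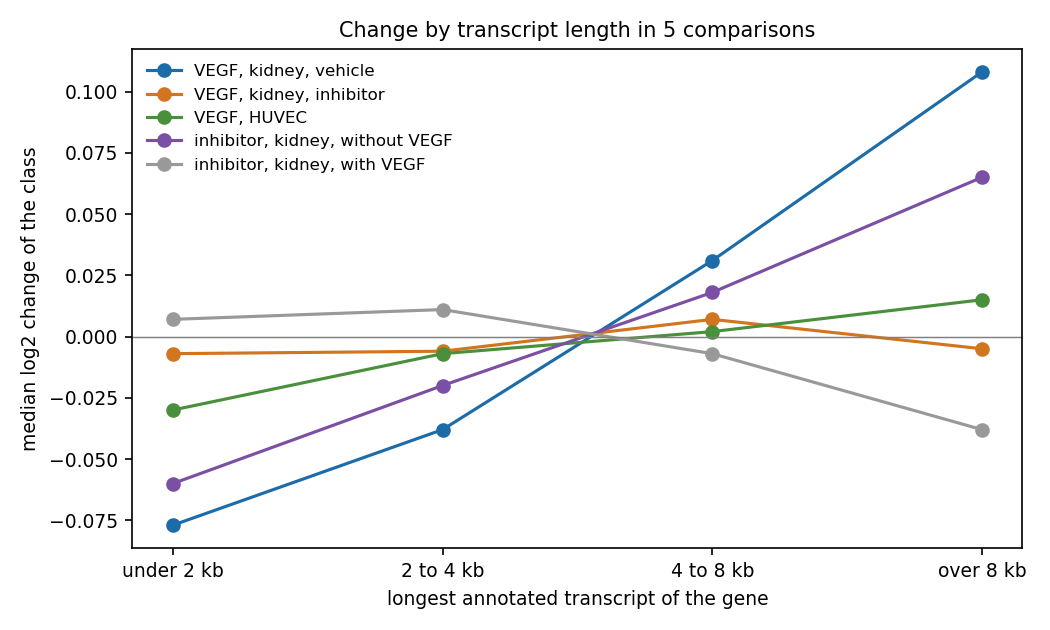
Median log2 change (y axis) of genes grouped by the length of their longest annotated transcript (x axis, 4 classes) for VEGF in kidney cells under vehicle, VEGF in kidney cells under inhibitor, VEGF in HUVEC, and the inhibitor in kidney cells without and with VEGF. The median of transcripts over 8 kb lay at 0.108, -0.005, 0.015, 0.065 and -0.038 in this order.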

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

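Of the tests below, the length and GC trend tests and the counts of splits were set out before their results were seen. All the others were chosen after. Within each group of 4 cultures a value was looked at again when its gap to the nearest other passed Dixon's 95% critical value as a share of the group's range. This held for 30 of 359 levels (18.0 by chance), for 9 of 151 log2 changes (7.6 by chance) and for 1 of 6 groups by depth (0.3 by chance). Of the levels, 12 stood apart in culture B, 8 in A, 5 in G, 2 in D, and 1 each in C, E and H.

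Culture B stood apart in matrix and mural genes of kidney cells under vehicle. Without VEGF it held the high value of COL6A3 (gap 0.953, 68130 against 4720 to 7693), COL1A1 (0.865, 98400 against 5146 to 17730), CSPG4 (0.861), PDGFRB (0.847), NOTCH3 (0.979) and MGP (0.921). With VEGF it held that of COL6A3 (0.945), COL1A1 (0.854) and CLU (0.952). Low counts gave gaps of 1 in HUVEC, where a single culture had reads of TNC, LPL or HEY2 without VEGF or of COL6A3 with VEGF. TAGLN (0.956, culture G), TRIB1 (0.963, G) and DUSP1 (0.865, E) stood apart in HUVEC without VEGF.

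Culture A held the high level of ANGPT2 under vehicle (0.883) and under the inhibitor with VEGF (0.845), of PLAU under vehicle (0.846) and inhibitor (0.839), of LPL (0.870), of DEPP1 under the inhibitor (0.906) and of CD274 under the inhibitor with VEGF (0.840), and the low level of DDIT4 under vehicle (0.899). Its VEGF response was the lowest for DLL4 (0.904, log2 change 0.33 against 0.85 to 0.91) and IL6 (0.970, 1.27 against 2.43 to 2.46), and for NR4A1 under the inhibitor (0.904). The inhibitor change of IRS2 without VEGF was the lowest in A (0.830). Culture B held the largest rise of NFKBIZ with VEGF (0.962) and the high level of EGR4 with VEGF (0.859), RCAN1 under vehicle (0.834) and BCL2L11 under the inhibitor (0.830). Culture C had the smallest fall of FBXO32 (0.917) and the low level of DLL4 (0.884) under the inhibitor without VEGF, and a DLL4 change apart from the others under the inhibitor with VEGF (0.831). Culture D had the low level of FOSL1 under vehicle (0.840), its largest rise under the inhibitor with VEGF (0.953), and the only reads of EGR2 under the inhibitor without VEGF (gap 1). The VEGF change of ESM1 in HUVEC lay apart in culture H (0.926, log2 change -0.25 against 0.06 to 0.09). By depth, the inhibitor group without VEGF had 1 library at 14.6 M reads (0.882).

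Many but not all fibroblast and mural cell transcripts were higher in the kidney cultures than in HUVEC without VEGF. RGS5 was higher in HUVEC (mean of 13792 against 2275), and LUM averaged higher there (104.5 against 22.4). Neither list was called with an estimated correlation (camera adjusted p = 0.449 for fibroblast and p = 0.367 for mural markers). Of 5 abundant fibroblast transcripts 1 (COL1A1) lay higher in every kidney than in every HUVEC culture, while COL1A2, COL3A1, DCN and LUM overlapped. The fibroblast markers PDGFRB, THY1 and FAP, outside these 5, were higher in every kidney culture. HUVEC held COL1A2 and COL3A1 too (means of 1259 and 660.1), so the overlap cannot decide on fibroblasts alone in every kidney culture. Of 14 measured fibroblast and mural members, 9 were higher in every kidney culture. These are the genes and libraries that raised the question, so the count does not bear on a source. Fibroblasts and mural cells among the cultured cells stayed open. A lower endothelial share was left open, since 0 of 12 pan-endothelial markers were lower in kidney cells by the test but 8 were lower on average (median log2 difference 0.41, HUVEC over kidney, -0.39 to 1.59). Expression by kidney endothelial cells in culture stayed open and untested, and tissue was confounded with donor and culture.

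The VEGF response of EGR1 was larger in HUVEC than in kidney cells (adjusted p = 0.0476). A trend of length and GC content was argued against as the whole cause, since the log2 difference was 1.56 before (SE 0.20) and 1.47 after the trend was removed (SE 0.20, adjusted p = 0.0433). EGR1 was lower in HUVEC before VEGF (log2 difference -1.97, SE 0.50) and did not pass with VEGF (-0.40, SE 0.51). The difference in response is the gap with VEGF less that without, so a higher starting level in kidney cells and a smaller induction cannot be told apart. The 5 lists that shifted the same way, with the preset correlation only, were immediate early (adjusted p = 1.62e-06), ERK feedback (8.21e-07), NFAT (4.78e-05), glycolysis (4.78e-05) and arterial genes (0.0244), and a tissue difference in signalling stayed open and untested.

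Other splits of the same libraries were counted for each result. The 4 kidney comparisons and VEGF in HUVEC, fitted on 8 libraries each, pair libraries by culture, and the 8 splits that part every pair are too few for a share under 0.05. Over these 8 the highest other count was 0, and the real counts were 324 for VEGF under vehicle, 169 under the inhibitor, 172 for the inhibitor without VEGF, 181 with VEGF, and 158 in HUVEC. The others of these 8 reverse some of the pairs, which leaves the effect in the residual, so a low count was likely in advance. The rest of the 32 splits keep pairs together and so leave the effect in the residual too. Over all 32 splits 1 gave as many, the real one. The highest others were 1, 0, 3, 1 and 3 in the same order, and 3 more splits could not be fitted. For HUVEC against kidney cells 1 of 35 splits, the real one, gave as many, with real and highest other counts of 1279 and 183 without VEGF, and 1216 and 0 with VEGF. If the HUVEC donors are the 2 of the donor label, 15 splits are left, too few for a share under 0.05. For the difference between tissues in response, fitted on 1 change per culture (35 splits, 35 as large), and for that between inhibitor and vehicle (8 sign flips, 8 as large), the real and highest other counts were 0. Every split matches a count of 0, so these say nothing about chance.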

How the results depend on the processing

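The fits with a length and GC trend removed and without the 2 shallowest libraries were chosen after the data were seen, and all other alternatives before. The cause of the changes below was not tested, except that leaving out libraries and averaging leave fewer samples. Of 3879 values of named genes 3525 stayed on the same side of the threshold, 326 lost and 28 gained a call. Direction was compared only where the main or the alternative setting made a call, and there 0 reversed. Values called in neither may have changed sign.

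Leaving out 1 culture gave 142 to 599 genes for VEGF under vehicle in kidney cells (330 in full), 105 to 178 under the inhibitor (186), 112 to 185 for the inhibitor without VEGF (306), 53 to 149 with VEGF (145), 158 to 214 for VEGF in HUVEC (205), 0 to 7 for the difference between tissues in response (1), and 723 to 1059 and 718 to 1172 for HUVEC against kidney cells without and with VEGF (1279 and 1216). The difference between responses under inhibitor and vehicle had 0 in each.

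Without the culture block, that is without pairing, the counts were 22 for VEGF under vehicle, 26 under the inhibitor, 2 and 0 for the inhibitor without and with VEGF, 46 for VEGF in HUVEC and 0 for the difference between tissues. Gene list calls numbered 64, of which 20 held with an estimated correlation. Of the 44 calls from blocked fits 30 held without the block.

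DESeq2 gave 507 genes for VEGF under vehicle, 227 for the inhibitor with VEGF, 14 for the inhibitor by VEGF difference, 12 for the difference between tissues, and 2304 and 2254 for HUVEC against kidney cells. Without the 2 shallowest libraries the counts were 117 for VEGF under the inhibitor and 183 and 83 for the inhibitor without and with VEGF. With only its 8 libraries the inhibitor without VEGF had 172. HUVEC averaged by donor label gave 12 for the difference between tissues, 585 and 697 for HUVEC against kidney cells. That difference had 0 genes with a pseudocount of 0.5, without a filter, with a mean of at least 50 and with quantile normalisation, 3 with a pseudocount of 5 and with edgeR, and 2 with the trend removed. With limma 1305 genes had an unadjusted p under 0.05 in the main setting. Without a filter on low values HUVEC against kidney cells had 1331 genes without VEGF and 1288 with VEGF, 1128 and 1072 of them shared with the main setting. The shallowest library held 11.7 M reads, and a group with 0 reads of a gene gives only a bound against 3 reads per library.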

Other observations

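The test of the length and GC trend was set out before its result was seen, and the other tests here after. In kidney cells under vehicle, transcripts over 8 kb were low without VEGF and high with it, with a median log2 deviation from the mean of the culture of -0.051 ± 0.014 (SD, n = 4) and 0.051 ± 0.036, against 0.011 ± 0.013 and 0.008 ± 0.042 under the inhibitor. Their median log2 change was 0.104 ± 0.042 with VEGF under vehicle, 0.058 ± 0.007 with the inhibitor without VEGF, 0.001 ± 0.049 with VEGF under the inhibitor and, in the model fit, -0.038 with the inhibitor with VEGF. An effect of VEGF itself, whatever the cells and the inhibitor, was argued against, since their median change was -0.005 under the inhibitor and 0.015 in HUVEC, and low depth as the cause of the low values was too, since the vehicle library without VEGF was the shallowest in 1 of 4 cultures. For VEGF under vehicle a trend of length and GC content between libraries may account for many of the smaller calls: of 159 genes called under vehicle but not under the inhibitor, 44 kept their call after the trend was removed, and their median log2 change went from 0.33 (quartiles 0.27 to 0.42) to 0.21 (0.14 to 0.30), while 135 of 146 genes called under both kept theirs, as did 90 of 117 higher and 177 of 189 lower genes with the inhibitor without VEGF. The 159 genes were picked for passing in 1 comparison and not in the other, and changed less than the 146 (median 0.33 against 0.82 before removal). Such smaller calls are lost more readily with any change of the values, so the shares kept cannot by themselves show the trend as the cause. Removing the trend would also remove a real effect on long transcripts, and an effect of the inhibitor on them, or on their response to VEGF, stayed open and untested.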
